A study of Danio rerio with 37 samples.

How the data were processed

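RNA was measured in 37 libraries from zebrafish whole embryos collected 6 hours after fertilization. The labels name 3 RNA-targeting CRISPR effectors (RfxCas13d, DjCas13d and Cas7-11), 2 doses of GFP (10 pg and 50 pg) and a control and a knockdown arm for each, which gives 12 groups. Groups were taken from the sample titles. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a directional (strand-marking) kit. Per the submitters' processing notes, the genome build was danRer11. The aligner, the counting program and its strand setting are not given in the sources used here. What the control embryos received is not stated in the labels.

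The authors deposited 1 table of raw counts and 1 table of TPM values for each library. The deposited counts are whole numbers of reads per gene for 32520 genes, not normalized, followed by 4 summary entries for unmapped, multimapping, unassigned and ambiguous reads. Those entries held 17.3% to 26.4% of the reads and were kept out of library sizes and tests. The deposited TPM values (abundance of a transcript relative to its library) sum to between 999998.8 and 1000001.1 in each library and include GFP in all 37 libraries. The count tables listed GFP in 23 libraries, those of RfxCas13d and DjCas13d, so GFP was compared between all groups in TPM. Gene symbols came from the deposited tables for 20859 genes and from a gene name table for a further 8382. Gene positions were not used here. Reads that map to several places stood outside the gene counts, so values of genes with near-identical copies, such as hsp70l, keratins and egg coat (zp) genes, are uncertain. The same holds for overlapping and antisense genes, because the strand setting of the counting is not known here.

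Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 12 groups, which left 16321 genes, libraries were scaled by TMM, and all 37 libraries entered 1 quasi-likelihood fit (robust) with a coefficient per group. The biological coefficient of variation was 0.253. There were 15 contrasts: knockdown against control in each effector and dose, differences of these responses between doses and, at 50 pg, between effectors, and the 50 pg against the 10 pg controls. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a contrast, with a threshold of 0.05. All log2 fold changes, SEs and adjusted p-values of genes are from this test unless another tool is named. GFP in TPM was tested with limma 3.58.1 on log2(TPM + 1), which understates changes of low values. It was also tested with a two-sided exact permutation test of the difference between group means of log2(TPM + 1). A sum of counts over a group at 0 was given a floor of 3 reads over the group, and a fold against it is a lower bound that covers counting error only.

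Genes are named by a rule fixed, with the groups, tests, alternatives and lists, before the data were examined. For knockdown against control these are the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean log2 CPM of at least 1, no overlap between the arms' libraries and a gene name rather than a clone identifier. For other contrasts they are the 5 largest in each direction, without the overlap condition. The rule adds GFP, the members of each gene list with the smallest adjusted p (up to 4), and mdm2, cdkn1a, hsp70l, atf3 and ddit3 in every contrast. A further gene of the rule and 1 gene list are not reported here. Tests were made on 25 gene lists with camera (preset correlation between genes of 0.01, adjusted over the 25 lists of a contrast), again with an estimated correlation, and with fry. Camera asks whether a list moved differently from the other genes, and fry whether it moved at all. Some genes are in more than 1 list.

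The fit was tested on simulated counts with the library sizes of these libraries and 200 changed genes per contrast among 16321. Before these changes each gene had the same mean and spread in all groups. Of genes changed 2-fold, 29.9% were recovered at 50 pg RfxCas13d, 28.4% at 50 pg DjCas13d and 38.8% at 50 pg Cas7-11. Of genes changed 4-fold, 80.3%, 78.8% and 84.8% were recovered. At 10 pg, the shares for 2-fold changes were 29.9%, 44.8% and 62.7%. False calls made up 2.3% to 7.1% of the calls of a contrast. In the data 58.78% of genes passed at 50 pg RfxCas13d, and groups may differ in spread. The simulated shares therefore do not give the recovery in the real contrasts.

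Replicate numbers in the titles were checked for pairing by correlating, across genes, the deviations of same-numbered control and knockdown libraries from their group means. With Cas7-11 at 10 pg all 4 pairs correlated above 0.1, at 0.28 to 0.51, and the numbers were taken to pair these libraries. Unlike numbers correlated similarly, however: knockdown 1 with control 2 at 0.41, 3 with 4 at 0.29 and 4 with 3 at 0.45. Knockdown 1 with control 3 was at -0.47. Replicates 1 and 2 thus stood apart from 3 and 4, and single pairs cannot be told from these sets. The main fit models neither. In the other 5 comparisons the numbers did not pair. Alternatives were DESeq2 1.42.0, its kind of size factors within edgeR, library size alone as scaling, no filter on low counts, limma on log2(TPM + 1) and on log2(TPM + 0.1), only the libraries of the groups compared, the replicate number as a block, and leaving out each library in turn. Fits without the 5 libraries above 5000 CPM of malat1, and fits with only the libraries of 1 effector, were added after the data were seen. A test of miR-430 sites in transcripts was planned and not run, because no transcript sequences were used here.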

Results

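RNA of whole zebrafish embryos was sequenced 6 hours after fertilization, at the onset of gastrulation, in 37 libraries. The labels name RfxCas13d, DjCas13d or Cas7-11, which are CRISPR effectors that cleave RNA matched by a guide, 10 pg or 50 pg of GFP, and a control or a knockdown arm. They do not say what the controls received. The title of the series names RNA-targeting CRISPR-Cas technology in zebrafish. Its design text speaks of the clearance of maternal mRNAs after knockdown of primary miR-430, whereas the sample titles name GFP alone, so GFP was examined first. Each group had 3 libraries, except 2 for the 10 pg RfxCas13d knockdown and 4 for each arm of Cas7-11 at 10 pg. Reads assigned to genes (in units of 1e6) numbered 3.945 to 8.034 in the RfxCas13d libraries, 5.946 to 7.338 with DjCas13d and 17.4 to 24.0 with Cas7-11. Replicates were distinct libraries: over 40 pairs within groups, chi-square per degree of freedom was 3.44 to 67.1. The labels do not say that replicates came from separate clutches, so p-values measure the spread between these samples, which may be technical.

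Malat1, a long nuclear noncoding RNA, stood above 5000 CPM in 5 libraries: replicates 1 and 3 of the 10 pg RfxCas13d controls, replicate 1 of the 50 pg RfxCas13d controls, and replicates 1 and 2 of the 10 pg DjCas13d knockdown. The next highest library had 2272 CPM. In the 10 pg RfxCas13d controls, the 13 mRNAs encoded in mitochondria took 9.65% and 8.70% of reads in replicates 1 and 3 and 2.25% in replicate 2. With DjCas13d at 10 pg these took, in the knockdown, 5.74% and 5.34% in replicates 1 and 2 and 2.28% in replicate 3. In the Cas7-11 libraries malat1 was at 538 to 1156 CPM and these mRNAs at 1.48% to 2.18%.

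**Figure D1:**
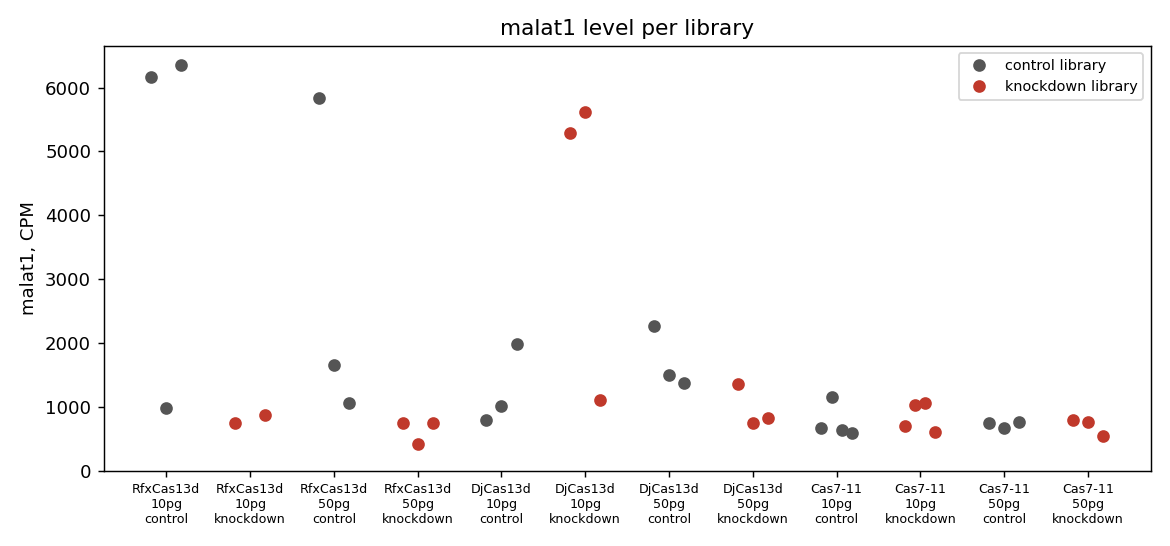
Malat1 level (CPM, linear axis) in each of the 37 libraries by group; each point is a library. The 5 libraries above 5000 CPM are 3 RfxCas13d controls and 2 libraries of the 10 pg DjCas13d knockdown.

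GFP was lower in every knockdown group than in its control group, and there was no overlap between libraries of the 2 arms in any of the 6 comparisons. With RfxCas13d its mean was 1980 ± 2150 TPM (SD, n = 3) in controls and 6.09 ± 2.59 (n = 2) in the knockdown at 10 pg, which is 99.7% lower. At 50 pg the means were 12300 ± 8960 and 232 ± 185 TPM (n = 3 each), 98.1% lower. With DjCas13d they were 3380 ± 251 and 15.7 ± 13.8 TPM at 10 pg, 99.5% lower, and 8800 ± 1440 and 62.3 ± 49.1 TPM at 50 pg, 99.3% lower (n = 3 each). With Cas7-11 they were 265 ± 35 and 52 ± 16 TPM at 10 pg (n = 4 each), 80.4% lower, and 1090 ± 342 and 261 ± 46.5 TPM at 50 pg (n = 3 each), 76.2% lower.

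In limma on log2(TPM + 1) over all genes, GFP fell with RfxCas13d at 10 pg and 50 pg (-7.62 ± 0.68 and -5.70 ± 0.61, SE; adjusted p = 5.94e-08 and 6.4e-09). It also fell with DjCas13d (-8.01 ± 0.61 and -7.37 ± 0.61; adjusted p = 1.06e-09 and 8.66e-09). With Cas7-11 the differences were -2.37 ± 0.53 and -2.02 ± 0.61, with adjusted p = 0.132 and 1 over all genes. GFP was named in advance, and its unadjusted limma p was 0.000105 and 0.00247. The SE rests on a spread pooled over all 37 libraries. The exact permutation p was 0.0286 for Cas7-11 at 10 pg and 0.1 in the other 5 comparisons, in each case the smallest that the number of libraries allows. With exchanges only within the 4 same-numbered pairs of Cas7-11 at 10 pg, a test chosen after the data were seen, the permutation p was 0.125, also the smallest possible. At 50 pg the response of GFP was larger with RfxCas13d than with Cas7-11 by -3.67 ± 0.87 (limma, adjusted p = 0.00105) and larger with DjCas13d than with Cas7-11 by -5.35 ± 0.87 (adjusted p = 0.00704). RfxCas13d and DjCas13d differed by 1.67 ± 0.87 (adjusted p = 0.128). Control GFP at 50 pg was 12300, 8800 and 1090 TPM with RfxCas13d, DjCas13d and Cas7-11, and the Cas7-11 libraries were deeper. The differences of the GFP response from Cas7-11 are thus confounded with GFP level and depth. Responses at the 2 doses differed by 1.92 ± 0.92 with RfxCas13d, 0.64 ± 0.87 with DjCas13d and 0.34 ± 0.81 with Cas7-11 (limma adjusted p = 0.0935, 0.676 and 1). In the counts of the 23 libraries that list it, GFP fell with RfxCas13d (-8.22 ± 1.18 and -6.16 ± 0.85) and with DjCas13d (-7.28 ± 0.91 and -7.22 ± 0.89; edgeR adjusted p = 0.00288, 1.39e-05, 0.00427 and 0.00374).

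**Figure D2:**
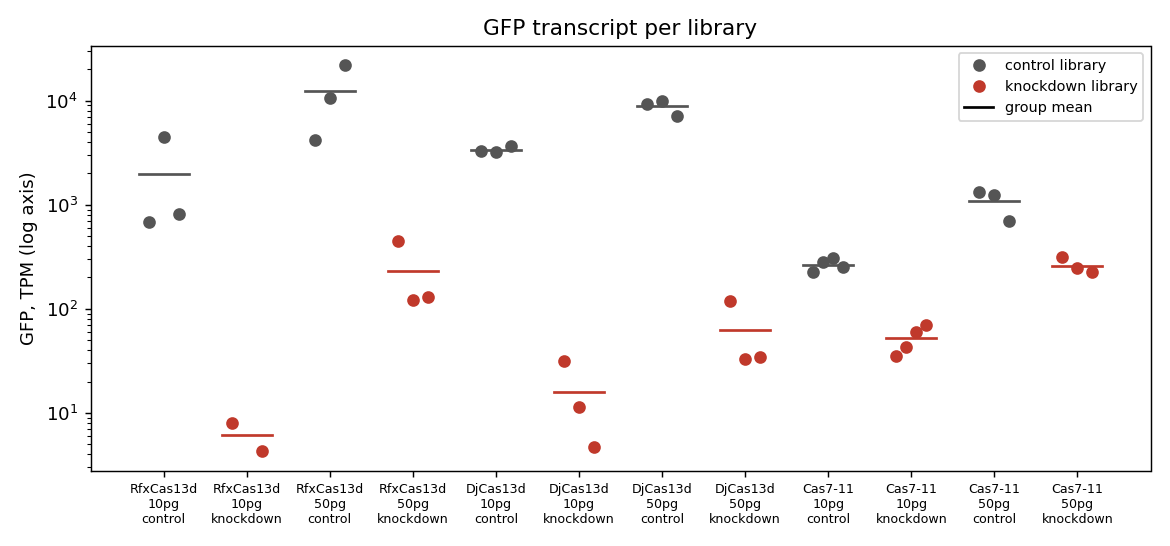
GFP level (TPM, log axis) in each library of the 12 groups; points are libraries and bars are group means. Means fell from 1980, 12300, 3380 and 8800 TPM in the RfxCas13d and DjCas13d controls to between 6.09 and 232 TPM, and with Cas7-11 were 265 and 1090 TPM in controls against 52 and 261 TPM.

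At 50 pg with RfxCas13d, many egg-supplied transcripts stood higher in the knockdown embryos, 29 of 43 rising and 9 falling, and most transcripts of the ribosome, the spliceosome and the patterned gastrula stood lower. Of the 15 lists that passed in camera only 2, ribosome biogenesis and ventral BMP signalling, passed with an estimated correlation (adjusted p = 0.0468 each). Of 16321 genes, 4900 rose and 4694 fell, 4016 and 3136 of them by 2-fold or more (n = 3 against 3). Btg4, which recruits a deadenylase during maternal mRNA clearance, rose by 5.19 ± 0.39 on the log2 scale (adjusted p = 1.92e-11), from 4.10 ± 1.65 to 152 ± 43.6 CPM (SD). Buc, the organizer of the Balbiani body in the oocyte, rose from 10.6 ± 1.88 to 331 ± 138 CPM and dazl, a germ cell RNA-binding protein, from 5.97 ± 0.448 to 87.1 ± 26.7 CPM. The mean of pes, a ribosome assembly factor, fell from 295 ± 41.1 to 49.1 ± 18.4 CPM.

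Besides btg4, the genes with the largest rises were tob2 (5.64 ± 0.61), a relative of btg4 in mRNA deadenylation, cdk5rap2 (5.25 ± 0.74), a centrosome protein, and f3b (5.23 ± 0.62), a tissue factor that starts coagulation. Others were inpp5f (5.16 ± 0.60), abr (5.16 ± 0.71) and the Argonaute gene ago3a (4.98 ± 0.56), with adjusted p of at most 6.39e-07. The rule also named nr4a1, tmem38a and abhd13, which had 1, 1 and 3 reads over the 3 control libraries and for which no fold is given. Their knockdown means were 3.43, 2.40 and 7.59 CPM. The largest falls were in dlx3b (-6.38 ± 1.23), a homeobox gene of the ectoderm, cdx1a (-5.27 ± 1.0), a posterior homeobox gene, mdkb (-5.22 ± 1.16), a growth factor, and a2ml (-5.21 ± 1.53). Further falls were in nova2 (-5.07 ± 1.0), a neural splicing factor, ugt1b5 (-5.02 ± 0.67), cyp2aa2 (-4.88 ± 0.65), tfa (-4.87 ± 0.81), which encodes transferrin, and ANGPTL5 (-4.82 ± 1.12), with adjusted p from 1.97e-07 to 0.00484. Hoxb1b, a hox gene of the gastrula, fell to 2 reads over the 3 knockdown libraries (5.57 ± 3.99 CPM in controls).

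Among 43 maternal mRNAs tested, 29 rose and 9 fell, and the list median was 2.29 (camera, adjusted p = 3.51e-05; adjusted p = 0.492 with an estimated correlation). The examples with the smallest p were btg4, cd82b (3.58 ± 0.29), buc (4.97 ± 0.46) and dazl (3.86 ± 0.37). Of 16 germ plasm and germ cell genes, 9 rose and 1 fell (adjusted p = 0.0308; adjusted p = 0.541 with an estimated correlation). Buc, dazl and the germ line linker histone h1m (2.60 ± 0.39) rose and the helicase ddx4 fell by 1.56 ± 0.23. Of 13 published miR-430 targets, 7 rose and 4 fell, among them btg4 and cd82b upward and msna (-1.47 ± 0.18) and lft1 (-1.60 ± 0.28) downward, and the list did not pass in camera (adjusted p = 0.235). These counts were the same when adjusted over the list alone.

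Of 79 cytosolic ribosomal protein genes, 78 fell, with a median of -1.76 (adjusted p = 4.05e-26; adjusted p = 0.347 with an estimated correlation). Examples were rpl7l1 (-1.50 ± 0.13), rpl3 (-2.17 ± 0.22), rps7 (-3.19 ± 0.32) and rps6 (-2.03 ± 0.21). The list was built from gene symbols and takes in the ribosomal-protein-like genes rpl7l1 and rpl22l1. Of 51 ribosome biogenesis factors, 45 fell and none rose, median -1.06 (adjusted p = 1.39e-16; adjusted p = 0.0468 with an estimated correlation), led by pes (-2.59 ± 0.20), bms1 (-1.83 ± 0.15), nhp2 (-1.64 ± 0.16) and npm1a (-1.49 ± 0.14). Of 45 spliceosome genes, 37 fell and none rose, median -1.04 (adjusted p = 6.73e-13; adjusted p = 0.275 with an estimated correlation), with snrnp70 (-1.44 ± 0.12), srsf1a (-1.44 ± 0.14), srsf3b (-2.05 ± 0.21) and sf3b3 (-1.55 ± 0.16). In these 3 lists 78, 45 and 37 fell, and 1 spliceosome gene rose, adjusted over the list alone.

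Genes that pattern the gastrula mostly fell. Of 22 genes of ventral BMP signalling, 19 fell and 1 rose, median -1.68 (adjusted p = 1.51e-07; adjusted p = 0.0468 with an estimated correlation), among them gata2a (-2.60 ± 0.22), eve1 (-2.80 ± 0.28), bambia (-2.06 ± 0.22) and id1 (-1.67 ± 0.22). Of 26 neural and epiblast genes, 20 fell and 2 rose (adjusted p = 0.000296; adjusted p = 0.347 with an estimated correlation). Zic2b, sox11a and sox2 fell by 1.83 ± 0.18, 1.71 ± 0.19 and 2.45 ± 0.29, while her5, a repressor of the mid-hindbrain domain, rose by 2.70 ± 0.23. Of 31 mesendoderm and Nodal genes, 16 fell and 6 rose (adjusted p = 0.0262; adjusted p = 0.541 with an estimated correlation). Mespab, mespaa and tbx16 fell by 2.80 ± 0.31, 2.83 ± 0.32 and 1.27 ± 0.16, and eomesa, a maternally supplied T-box gene, rose by 4.14 ± 0.39. Of 17 dorsal organizer genes, 9 fell and 1 rose (adjusted p = 0.0298; adjusted p = 0.541 with an estimated correlation), with nog1 (-2.59 ± 0.47), fgf8a (-1.23 ± 0.23), sp5l (-2.32 ± 0.43) and shha (-3.56 ± 0.81). Of 14 FGF feedback genes, 8 fell and 2 rose (adjusted p = 0.025; adjusted p = 0.492 with an estimated correlation), with etv5b, dusp6, spry2 and spred1 at -1.40 ± 0.17, -1.53 ± 0.19, -1.45 ± 0.21 and -1.56 ± 0.26. Of 39 genes of zygotic genome activation, 23 fell and 8 rose (adjusted p = 0.000428; adjusted p = 0.347 with an estimated correlation), among them tfap2c (-3.12 ± 0.25), gata2a and zic2b downward and her5 upward. The counts lower and higher were, adjusted over the list alone, 19 and 1, 21 and 2, 17 and 6, 9 and 1, 8 and 2, and 23 and 8.

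Of 29 genes of the enveloping layer, the outer epithelium of the embryo, 22 fell and 3 rose (adjusted p = 1.38e-06; adjusted p = 0.275 with an estimated correlation). The keratins krt4 and krt8 fell by 2.32 ± 0.27 and 1.66 ± 0.21, cldne by 1.49 ± 0.18 and capn9 by 1.66 ± 0.21. Of 18 genes of the yolk syncytial layer, 12 fell and 2 rose (adjusted p = 0.0262; adjusted p = 0.541 with an estimated correlation). The apolipoproteins apoc1 (-2.71 ± 0.34), apoeb (-1.84 ± 0.27) and apoa1a (-4.41 ± 0.83) fell, and mxtx2, a regulator of that layer, rose by 4.98 ± 0.77. Of 42 cell cycle genes, 24 fell and 6 rose, with a median of -0.58 that was 0 when scaled by library size alone (adjusted p = 0.0293; adjusted p = 0.541 with an estimated correlation), with bub1bb (-1.19 ± 0.14), mcm3 (-1.79 ± 0.26) and ccne2 (-1.27 ± 0.19) lower and birc5b (3.26 ± 0.46) higher. Of 42 nuclear genes of oxidative phosphorylation, 18 fell and 5 rose, with a median of -0.44 that was 0.17 when scaled by library size alone (adjusted p = 0.00846; adjusted p = 0.541 with an estimated correlation), led by uqcrfs1 (-1.97 ± 0.15), ndufa5 (-1.58 ± 0.17), cox7c (-1.61 ± 0.21) and ndufs6 (-1.87 ± 0.27). None of the 13 mitochondrially encoded mRNAs passed (list adjusted p = 0.932). In these 5 lists 22, 13, 24, 18 and 0 fell and 3, 2, 6, 5 and 0 rose, adjusted over the list alone.

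Stress genes moved both ways, and none of the following lists passed in camera. By fry 20 of 25 lists passed, against 15 in camera. The added ones were the integrated stress, heat shock, RNA decay, miR-430 target and nuclear noncoding RNA lists (fry adjusted p = 7.61e-05, 0.00283, 3.28e-05, 0.00587 and 0.00837). Since 9594 of 16321 genes passed here, a pass by fry alone does not set a list apart from the other genes. Of 21 genes of the integrated stress and unfolded protein responses, 12 rose and 3 fell (adjusted p = 0.0716). The chaperones hspa5 (1.65 ± 0.18) and hsp90b1 (1.67 ± 0.25) and the transcription factor atf3 (2.71 ± 0.41) rose, and atf4a fell by 1.98 ± 0.31. Ddit3 rose by 1.77 ± 0.64. Cdkn1a, a cell cycle inhibitor, rose by 2.56 ± 0.54, and mdm2 was at 0.08 ± 0.33 (adjusted p = 0.853). Of 18 heat shock genes, 2 rose and 6 fell (adjusted p = 0.225), with hspa8 (-1.14 ± 0.14), hspb1 (-1.86 ± 0.33) and hspa4a (-0.59 ± 0.15, but 0.01 scaled by library size alone and 0.18 by limma on TPM) lower, dnajb1a (1.47 ± 0.36) higher and hsp70l at 0.35 ± 2.04 (adjusted p = 0.894). Of 19 immediate early genes, 8 rose and 4 fell (adjusted p = 0.605), with ier2b (1.70 ± 0.41) and dusp5 (2.36 ± 0.58) higher and ier5 (-1.53 ± 0.21) and btg1 (-0.71 ± 0.18) lower. Of 21 genes of innate immunity, 5 rose and 2 fell (adjusted p = 0.668). Nfkbie rose by 1.75 ± 0.33. Nfkbiab fell by 0.71 ± 0.17, but was at 0.02 by limma on TPM and at -0.11 scaled by library size alone, and passed in neither. Irf3 had 1 read in the controls against a mean of 3.23 CPM in the knockdown, and pkz, with 0 reads in the controls, was at least 11-fold higher. Of 46 RNA decay factors, 10 rose and 15 fell (adjusted p = 0.159), with xrn1, dcp2 and cnot1 at -1.59 ± 0.18, -1.60 ± 0.19 and -1.32 ± 0.16 and parn at 1.56 ± 0.18. Of 20 apoptosis effectors, 8 rose and 6 fell (adjusted p = 0.721), with bida (-2.03 ± 0.22), mcl1a (-1.30 ± 0.16) and birc2 (-1.82 ± 0.26) lower and cflara (2.77 ± 0.45) higher. Of 2 nuclear noncoding RNAs, malat1 fell by 2.79 ± 0.63, and by 1.65 without the malat1-rich control replicate 1 (list adjusted p = 0.36). Adjusted over the list alone, 12, 2, 9, 5, 10, 8 and 0 rose and 4, 5, 4, 2, 15, 7 and 1 fell in these 7 lists.

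Without the malat1-rich libraries 9259 genes passed, and with only the 6 libraries compared 6012. TMM factors were 0.822 to 0.967 in these controls and 1.155 to 1.416 in the knockdown. Scaled by library size alone, 74.5% of the 9907 genes called were higher, against 4900 of 9594. The median of all genes was then 0.636, relative to which the medians of all lists reported here kept their sign.

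**Figure D3:**
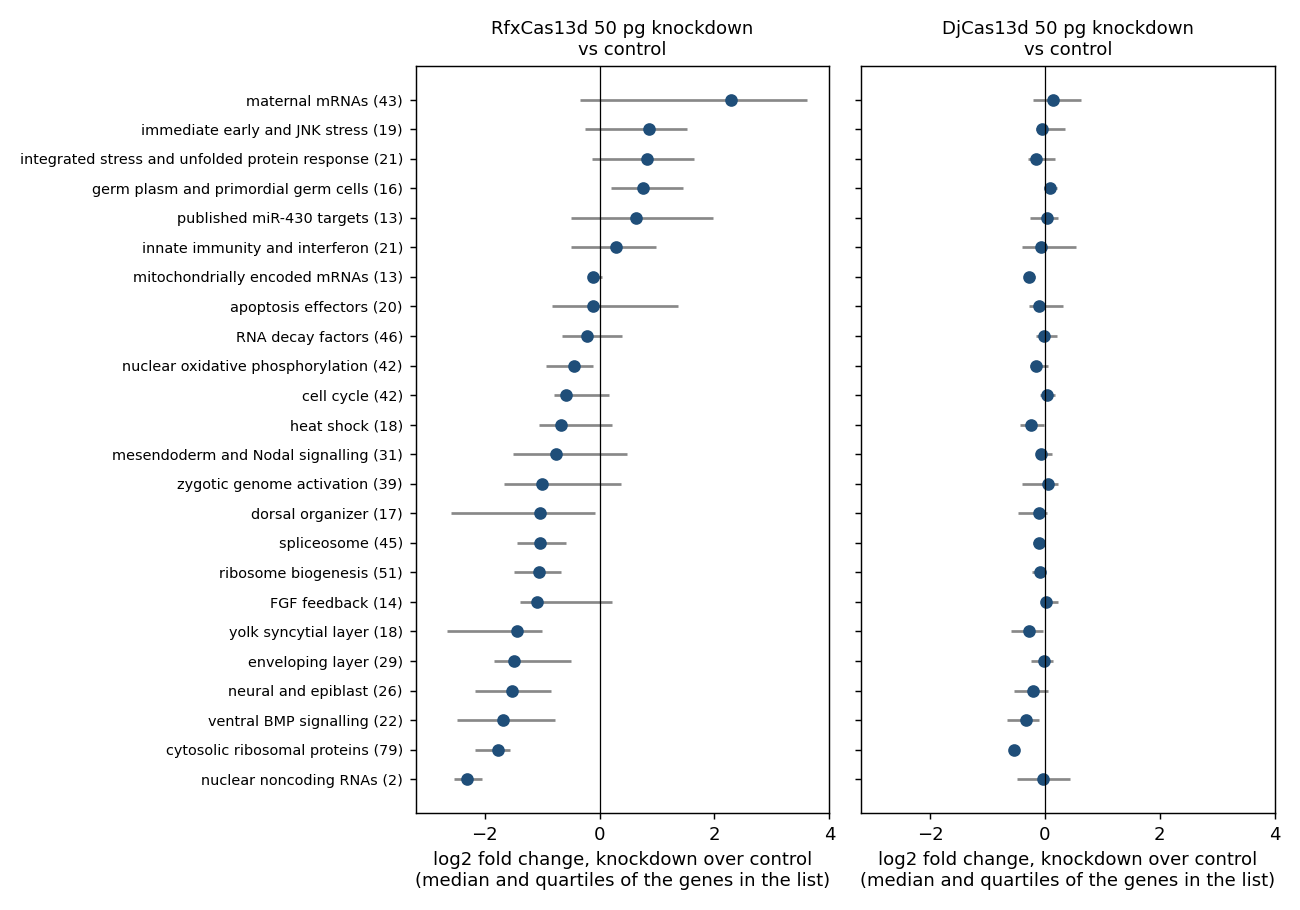
Median log2 fold change of the members of each gene list (horizontal axis) for knockdown against control at 50 pg with RfxCas13d (left) and DjCas13d (right), with the quartiles of the members as lines and the number of genes in brackets. With RfxCas13d at 50 pg the medians run from 2.29 for maternal mRNAs to -1.76 for ribosomal proteins and -2.30 for the 2 nuclear noncoding RNAs.

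At 10 pg with RfxCas13d, mRNAs encoded in mitochondria and those of ribosomal proteins were lower in the knockdown than in controls that were mostly malat1-rich. Maternal mRNAs did not rise. All 13 mitochondrial mRNAs fell, with a median of -2.0 (camera, adjusted p = 9.58e-10; adjusted p = 0.861 with an estimated correlation), among them mt-co2 (-2.54 ± 0.51), mt-nd3 (-2.47 ± 0.54), mt-cyb (-2.33 ± 0.56) and mt-co1 (-2.0 ± 0.48). Of 79 ribosomal protein genes, 38 fell and none rose, median -0.90 (adjusted p = 1.89e-20; adjusted p = 0.861 with an estimated correlation), with rpl22l1 (-1.63 ± 0.37), rps20 (-1.50 ± 0.36), rps26 (-1.33 ± 0.33) and rps7 (-1.35 ± 0.34). In all, 1142 genes rose and 1139 fell (n = 2 against 3), a balance that depends on the scaling. It was 1335 and 759 with library size alone, where the median of all genes was 0.123, and 2672 and 608 by limma on log2(TPM + 1), where it was 0.239. Of the control libraries, 2 of the 3 were malat1-rich: malat1 fell by 2.62 ± 0.74 (adjusted p = 0.0201). Mitochondrial mRNAs took 9.65% and 8.7% of reads in those 2 controls and 2.25% in control replicate 2. In the knockdown they took 1.68% and 1.74%. The list tests were not repeated without the malat1-rich libraries.

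Of 43 maternal mRNAs, 6 fell and none rose (adjusted p = 0.00627; adjusted p = 0.89 with an estimated correlation), among them npm2b (-1.43 ± 0.26), the egg coat genes zp3a.1 (-1.02 ± 0.27) and zp2.1 (-1.46 ± 0.44), and npm2a (-1.29 ± 0.42). Of 22 ventral BMP genes, 6 fell (adjusted p = 0.00916; adjusted p = 0.861 with an estimated correlation), with smad7 (-1.16 ± 0.25), id2a (-1.09 ± 0.23), bmp2b (-0.65 ± 0.17) and bambia (-0.88 ± 0.25). Of 42 cell cycle genes, 12 rose and 1 fell (adjusted p = 0.00883; adjusted p = 0.89 with an estimated correlation). The kinesins kif11 (1.15 ± 0.23) and kif20a (0.91 ± 0.22) and the checkpoint kinase bub1 (1.32 ± 0.32) rose. Of 18 heat shock genes, hspe1 (1.24 ± 0.34) and bag3 (1.2 ± 0.39) rose (adjusted p = 0.0453; adjusted p = 0.861 with an estimated correlation). The counts higher and lower were, adjusted over the list alone, 0 and 13 for mitochondrial mRNAs, 0 and 62 for ribosomal proteins, 0 and 6 for maternal mRNAs, 1 and 8 for BMP genes, 12 and 2 for the cell cycle and 4 and 0 for heat shock. A further 18 lists did not pass. Mdm2, cdkn1a, hsp70l, atf3 and ddit3 were at 0.77 ± 0.36, 1.05 ± 0.60, 4.0 ± 1.80, -0.02 ± 0.45 and 0.88 ± 0.69, with adjusted p of at least 0.129.

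The largest rises at this dose were in cd34 (4.57 ± 1.41), which encodes a surface protein of blood progenitors and endothelium, tbx6 (3.78 ± 1.16), a T-box gene of the paraxial mesoderm, EMILIN2 (3.78 ± 0.69), stbd1 (3.71 ± 0.81), SOGA1 (3.65 ± 1.0), the riboflavin transporter gene slc52a3-2a (3.41 ± 0.76), the adenosine receptor gene adora2ab (3.39 ± 0.88), CPEB2 (3.30 ± 0.63), ANO5 (3.21 ± 0.66) and slc25a22a (3.21 ± 0.78). The largest falls were in RIC3 (-4.13 ± 0.86), a chaperone of acetylcholine receptors, pcp4l1 (-4.11 ± 0.71), the sorting nexin gene snx6 (-3.57 ± 0.78), ifi27.4 (-3.14 ± 0.57), bbs4 (-3.06 ± 0.62), the glycolytic enzyme gene tpi1a (-3.04 ± 0.82), ONECUT2 (-2.88 ± 0.76), hvcn1 (-2.75 ± 0.55) and tstd3 (-2.74 ± 0.61). The adjusted p of these genes was between 0.00125 and 0.0313. Sncga, also named by the rule, had 3 reads in the knockdown against a mean of 9.78 ± 3.52 CPM in controls. No overlap between arms, which all of these genes show by the rule, arises by chance in 20% of groupings of 2 against 3. The count of 2281 genes became 1 without the malat1-rich libraries, which left 1 control, and 0 with only the RfxCas13d libraries or only the 5 compared (edgeR, with 2810 and 3573 genes at an unadjusted p under 0.05; DESeq2 on all libraries called 3025). It was 133 and 186 without replicate 1 or 2 of the knockdown, and 478, 4522 and 563 without replicate 1, 2 or 3 of the controls.

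The RfxCas13d responses at the 2 doses differed in 6645 genes, 3230 with a higher and 3415 with a lower response at 50 pg. The largest positive differences were in trim35-29 (6.55 ± 1.04), tango2 (5.88 ± 0.77), ftr81 (5.62 ± 0.89) and phactr2 (5.49 ± 1.09), and the largest negative ones in twist2 (-6.44 ± 1.88), nova2 (-6.28 ± 1.30), dlx3b (-6.26 ± 1.65) and cdx1a (-6.25 ± 1.32), with adjusted p from 1.56e-06 to 0.00743. Nr4a1 and hoxb1b were also named and had too few reads for a fold. Atf3 responded more at 50 pg by 2.72 ± 0.61 (adjusted p = 0.000808), and cdkn1a, mdm2, ddit3 and hsp70l did not pass. Across genes, which are not independent replicates, fold changes at the 2 doses had r = 0.07. There were 398 genes higher at both doses (343 expected of independent lists), 558 lower at both (328 expected) and 401 in opposite directions. Without the malat1-rich libraries 4345 genes differed.

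With DjCas13d at 50 pg, bckdk, the kinase that inhibits breakdown of branched-chain amino acids, fell by 1.08 ± 0.17 on the log2 scale (adjusted p = 0.00562, n = 3 against 3), from 363 ± 19 to 171 ± 9.11 CPM (SD), and was the 1 gene of 16321 that passed. Without knockdown replicate 2 or 3 it did not pass (-1.07 and -1.06; adjusted p = 0.11 and 0.127). The 79 ribosomal protein mRNAs were lower as a list, with a median of -0.54 and 78 of 79 below 0 (camera, adjusted p = 5.92e-27; adjusted p = 0.952 with an estimated correlation). Ventral BMP genes had a median of -0.33 (adjusted p = 1.35e-05; adjusted p = 0.299 with an estimated correlation), and 5 of 22 were lower adjusted over the list alone. Ribosome biogenesis and spliceosome genes had medians of -0.09 and -0.11 (adjusted p = 0.0429 each; adjusted p = 0.952 with an estimated correlation), which turned to 0.04 and 0.02 when scaled by library size alone. That scaling moved the median of all genes to 0.136, relative to which the 2 lists were at -0.09 and -0.12. Maternal mRNAs had a median of 0.14 and did not pass as a list (camera, adjusted p = 0.312). Adjusted over the list alone, 1 of 43 maternal mRNAs rose: btg4 was at 3.49 ± 0.355 CPM in controls and 10.3 ± 3.04 CPM in the knockdown (adjusted p = 0.178 over all genes). Mdm2, cdkn1a, hsp70l, atf3 and ddit3 lay between -0.44 ± 1.31 and 0.71 ± 0.60 (adjusted p of at least 0.725). In edgeR 1528 genes had an unadjusted p under 0.05, against 816 by chance, and DESeq2 called 42; the count was 0 with only the DjCas13d libraries and 979 with only the 6 libraries compared.

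With DjCas13d at 10 pg no gene passed in edgeR, with 2553 genes at an unadjusted p under 0.05 and 104 called by DESeq2. As lists, mitochondrial mRNAs (median 1.18; adjusted p = 1.48e-08; adjusted p = 0.982 with an estimated correlation) and ribosomal protein mRNAs (median 0.56; adjusted p = 2.38e-19; adjusted p = 0.982 with an estimated correlation) were higher, and cell cycle genes lower (median -0.22; adjusted p = 0.00229; adjusted p = 0.982 with an estimated correlation). Adjusted over the list alone, all 13 mitochondrial mRNAs rose and no ribosomal protein or cell cycle gene passed. Mitochondrial mRNAs took 5.74% and 5.34% of reads in malat1-rich knockdown replicates 1 and 2. They took 2.28% in replicate 3, within the 1.84% to 2.69% of the controls. The list tests were not repeated without the malat1-rich libraries. Malat1, scaled by TMM, was at 1310 ± 667 CPM in controls and 4600 ± 3030 CPM in the knockdown (adjusted p = 0.199), with replicates 1 and 2 of the knockdown malat1-rich. Bckdk was at -0.50 ± 0.17 (adjusted p = 0.198), and mdm2, cdkn1a, hsp70l, atf3 and ddit3 were between -1.0 ± 0.56 and 0.25 ± 1.37 (adjusted p of at least 0.384). Without replicate 3 of the knockdown, the library low in malat1, 2643 genes passed. The DjCas13d responses at the 2 doses differed in 0 genes in edgeR, with 2877 at an unadjusted p under 0.05, 214 in DESeq2, and 2287 in edgeR without the same library.

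With Cas7-11, a small set of transcripts fell at both doses. Of the 11 genes that fell at 10 pg (n = 4 against 4) and the 10 that fell at 50 pg (n = 3 against 3), 7 were shared, where independent lists would share 0.00674: ostf1, zgc:91910, pdlim1, aga, iars2, hnrnpm and zgc:100918. Ostf1, an adaptor protein of osteoclast signalling, fell by 1.40 ± 0.21 and 1.81 ± 0.24 (adjusted p = 0.000642 and 8.15e-05). Pdlim1, a cytoskeletal adaptor, fell by 1.26 ± 0.19 and 1.24 ± 0.22, aga, a lysosomal amidase, by 1.05 ± 0.19 and 1.27 ± 0.22, iars2, the mitochondrial isoleucyl-tRNA synthetase, by 1.01 ± 0.17 and 1.22 ± 0.19, and hnrnpm, a splicing regulator, by 0.98 ± 0.15 and 0.86 ± 0.17, with adjusted p of at most 0.0314. The clone-named genes zgc:91910 and zgc:100918, which fall outside the naming rule and were chosen after their values were seen, fell by 1.28 ± 0.17 and 1.13 ± 0.12 at 10 pg and by 1.55 ± 0.20 and 1.30 ± 0.14 at 50 pg. The calls at 50 pg depended on single libraries and on the tool: leaving out any 1 of the 6 gave 4 to 7 genes, and limma called 2 or 3. Hnrnpm did not pass in any of those 6 fits, pdlim1 did not without control replicate 3 or knockdown replicate 2 or 3, and aga did not without knockdown replicate 1 or 2. At 10 pg aga did not pass without knockdown replicate 1 (adjusted p = 0.0638). Of the 7, 4 also fell with RfxCas13d: hnrnpm and zgc:100918 at 50 pg (-1.69 ± 0.17 and -0.40 ± 0.14; adjusted p = 2.88e-09 and 0.019), and ostf1 and zgc:91910 at 10 pg (-0.95 ± 0.27 and -0.77 ± 0.22; adjusted p = 0.0218 and 0.0214). Ostf1 and pdlim1 rose with RfxCas13d at 50 pg (1.13 ± 0.24 and 1.13 ± 0.22). Of the 10 genes lower with Cas7-11 at 50 pg, 4 were also lower with RfxCas13d at 10 pg (0.698 expected) and 3 with RfxCas13d at 50 pg (2.88 expected). For the 11 lower with Cas7-11 at 10 pg these were 2 (0.768 expected) and 3 (3.16 expected). Opposite calls with RfxCas13d at 10 and 50 pg numbered 0 and 3 for Cas7-11 at 50 pg. For Cas7-11 at 10 pg they numbered 1 and 4.

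Further genes that fell at 10 pg were pla2g15 (-1.07 ± 0.19), a lysosomal phospholipase, nme3 (-0.90 ± 0.18), NSMAF (-0.89 ± 0.18) and rab14 (-0.65 ± 0.12), and at 50 pg cnpy3 (-1.36 ± 0.27), stmn1a (-0.80 ± 0.16) and maf1a (-0.73 ± 0.14), with adjusted p from 0.00606 to 0.0381. With the replicate number as a block, 9 of the 12 calls at 10 pg passed again, and nme3, NSMAF and rab14 did not (-0.88, -0.87 and -0.65; adjusted p = 0.105, 0.326 and 0.105). Leaving out 1 library, nme3 passed only without control replicate 3, rab14 only without knockdown replicate 2 and NSMAF only without control replicate 1 or 2. Pla2g15 did not pass without knockdown replicate 4, nor nnt without control replicate 1 or 2 or knockdown replicate 3 or 4. At 50 pg cnpy3 passed in none of the 6 such fits (edgeR adjusted p of 0.0585 to 0.472). Stmn1a did not pass without control replicate 1 or 3, maf1a without control replicate 1 or 2, and both without knockdown replicate 1 or 2. Nnt, the mitochondrial transhydrogenase, rose by 0.84 ± 0.16 at 10 pg (adjusted p = 0.0189) and was at 0.90 ± 0.19 at 50 pg (adjusted p = 0.0504). At 10 pg germ plasm genes were higher as a list (median 0.21; adjusted p = 0.000729; adjusted p = 0.787 with an estimated correlation), as were mesendoderm genes (median 0.11; adjusted p = 0.0331; adjusted p = 0.787 with an estimated correlation), and ribosome biogenesis genes were lower (median -0.10; adjusted p = 0.00193; adjusted p = 0.787 with an estimated correlation). Heat shock genes were lower (median -0.17; adjusted p = 0.000369; adjusted p = 0.359 with an estimated correlation), 5 of 18 adjusted over the list alone. At 50 pg ribosome biogenesis genes (median -0.14; adjusted p = 4.21e-06; adjusted p = 0.932 with an estimated correlation) and mitochondrial mRNAs (median -0.37; adjusted p = 0.0288; adjusted p = 0.932 with an estimated correlation) were lower as lists. Apart from heat shock, no member of these lists passed adjusted over the list alone. Maternal mRNAs had medians of 0.04 and -0.13 at the 2 doses and miR-430 targets -0.04 and 0.00, and neither list passed. Mdm2, cdkn1a, hsp70l, atf3 and ddit3 had an adjusted p of 1 at both doses. The 2 doses differed in 0 genes in edgeR, with 200 at an unadjusted p under 0.05 against 816 by chance, and 0 in DESeq2. Knockdown against control gave 423 genes under that p at 10 pg and 525 at 50 pg. These counts are below chance, so the test was conservative for Cas7-11. Few calls therefore do not show an absence of change.

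**Figure D4:**
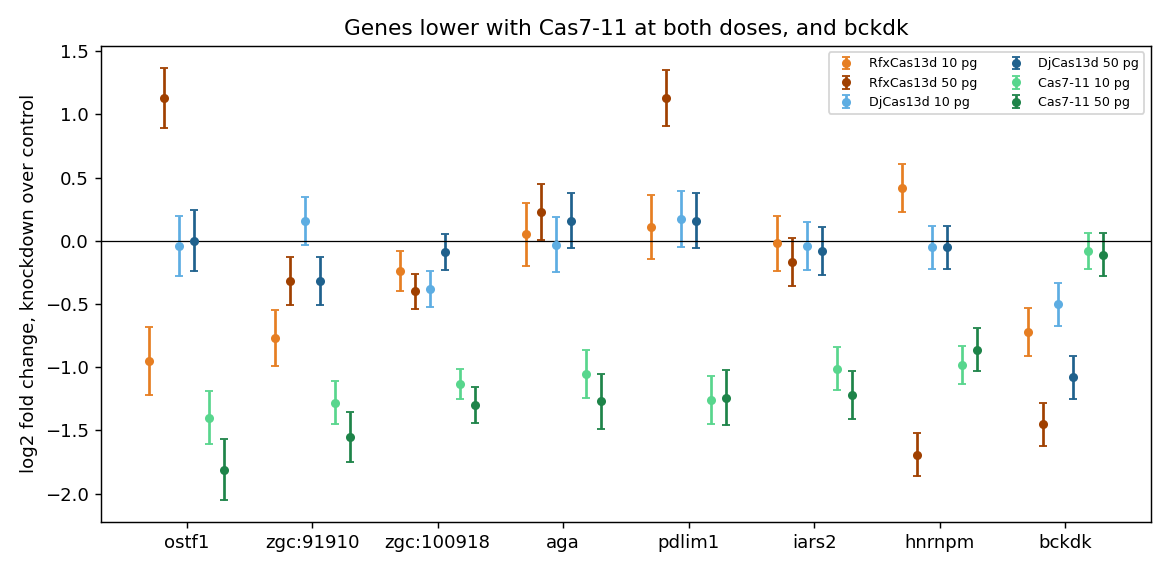
Log2 fold change of knockdown against control, with its SE, of the 7 genes that fell with Cas7-11 at both doses, and of bckdk, in each of the 6 comparisons. For the 7 genes the values with Cas7-11 lie between -0.86 and -1.81, those with DjCas13d between -0.38 and 0.17, those with RfxCas13d between -1.69 and 1.13, and bckdk is at -1.08 with DjCas13d at 50 pg.

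At 50 pg the response to the knockdown differed between RfxCas13d and DjCas13d in 5427 genes (2574 higher and 2853 lower with RfxCas13d) and between RfxCas13d and Cas7-11 in 7388 (3699 and 3689). This nominal dose gave unlike GFP levels: control means were 12300, 8800 and 1090 TPM with RfxCas13d, DjCas13d and Cas7-11. Differences from Cas7-11 are confounded with GFP level and with its greater depth. Against DjCas13d the largest positive differences were in f3b (4.99 ± 0.91), igfbp1a (4.89 ± 0.97), which binds insulin-like growth factors, and arhgap32a (4.84 ± 0.84), and the largest negative ones in NTRK2 (-5.17 ± 1.2), a neurotrophin receptor, ugt1b5 (-4.78 ± 0.83), dlx3b (-4.71 ± 1.62), tfa (-4.30 ± 1.02) and col10a1a (-4.27 ± 0.69), with adjusted p from 2.99e-05 to 0.0255. Against Cas7-11 they were f3b (5.76 ± 0.82), mxtx2 (5.75 ± 0.99), tob2 (5.69 ± 0.76) and abr (5.61 ± 0.87), and dlx3b (-7.09 ± 1.51), mdkb (-6.50 ± 1.47), nova2 (-6.09 ± 1.27), cdx1a (-5.93 ± 1.25) and a2ml (-5.75 ± 1.87), with adjusted p from 1.19e-06 to 0.0138. Nr4a1, named in both contrasts, and tmem38a, named in the first, had 1 read in the RfxCas13d controls. Atf3 responded more with RfxCas13d than with DjCas13d by 3.06 ± 0.58 and than with Cas7-11 by 3.13 ± 0.54 (adjusted p = 0.000185 and 3.52e-05). Cdkn1a differed from Cas7-11 by 2.92 ± 0.72 (adjusted p = 0.0016) and was at 1.90 ± 0.76 against DjCas13d (adjusted p = 0.0546). DjCas13d and Cas7-11 differed in zgc:100918 alone (1.21 ± 0.20, adjusted p = 0.019), with 868 genes at an unadjusted p under 0.05 against 816 by chance, and 22 called by DESeq2. That gene did not pass without a filter or with the block on replicates. In 9 of the 12 fits that left out 1 library of the 4 groups no gene passed in edgeR: those without any 1 DjCas13d or Cas7-11 control, DjCas13d knockdown replicate 1, or Cas7-11 knockdown replicate 1 or 2.

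Between controls, the RfxCas13d embryos at 50 pg and 10 pg of GFP differed in 277 genes, 118 higher and 159 lower at 50 pg. With library size alone 57 were higher and 202 lower, with a median of all genes of -0.12. Higher were smco4 (2.31 ± 0.57), the ferritin gene fthl28 (2.0 ± 0.52), PRORP (1.83 ± 0.48), a protein of mitochondrial RNase P, mrpl53 (1.58 ± 0.37) and hsd11b1la (1.37 ± 0.36), and lower were antxr1c (-3.29 ± 0.78), ALOX5 (-3.28 ± 0.80) and the sialyltransferase gene st3gal7, which had 0 reads in the 50 pg controls and was at least 43.6-fold lower, with adjusted p from 0.00249 to 0.0446. Tmem38a and nr4a1 were also lower, with 1 read each in the 50 pg controls. Without the malat1-rich libraries, 3 of the 6, no gene passed in edgeR (1717 at an unadjusted p under 0.05), and DESeq2 on all libraries called 693. Antxr1c then changed sign, to 0.17; its mean in the 10 pg controls was 10.2 ± 11.1 CPM. Without replicate 1, 2 or 3 of the 10 pg controls 63, 1215 and 34 genes passed, and without replicate 1, 2 or 3 of the 50 pg controls 92, 20 and 1008. The DjCas13d and Cas7-11 controls differed in 0 genes in edgeR, with 559 and 191 at an unadjusted p under 0.05 against 816 by chance, and in 0 in DESeq2. In limma on log2(TPM + 1), GFP rose with its dose in the RfxCas13d controls by 2.89 ± 0.61 (adjusted p = 0.0154, with 2.86 ± 0.73 and 0.112 in counts by edgeR), and was 1.37 ± 0.61 and 1.99 ± 0.57 higher in those of DjCas13d and Cas7-11 (adjusted p = 1 each), with exact permutation p = 0.2, 0.1 and 0.0286. The unadjusted limma p of GFP was 0.0331 in the DjCas13d and 0.00155 in the Cas7-11 controls.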

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

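The correlation of the Cas7-11 fold changes between doses, the fits without the malat1-rich libraries, the fits with only 1 effector and the sorting of groupings by whether they mix the arms were tests chosen only after the result was seen. The difference between groups is what singles out the following responses. The response to the knockdown differed between the doses of RfxCas13d in 6645 genes, and at 50 pg between RfxCas13d and DjCas13d in 5427, between RfxCas13d and Cas7-11 in 7388, and between DjCas13d and Cas7-11 in 1 (zgc:100918). The response of GFP differed by -3.67 between RfxCas13d and Cas7-11 and by -5.35 between DjCas13d and Cas7-11 (limma). Differences from Cas7-11 are confounded with its lower GFP level in controls and its greater depth. Of 100 groupings that exchange knockdown and control libraries within each of RfxCas13d and Cas7-11, the real one and 99 drawn at random, 1 (the real one) gave 7388 genes or more, the highest other giving 7369. For RfxCas13d against DjCas13d 8 of 100 gave 5427 or more (highest other 7534). In each contrast 8 groupings keep or exchange the RfxCas13d arms whole: these gave 6653 to 7388 and 5427 to 7534 genes, and the 92 that mix these arms at most 942 and 1656. The counts thus follow the RfxCas13d arms, and the groupings do not test chance. For DjCas13d against Cas7-11 14 of 100 gave 1 or more (highest other 3), all of them with the arms of 1 effector whole, and do not test it either. The dose differences of DjCas13d and Cas7-11 were 0 in edgeR (2877 and 200 genes at an unadjusted p under 0.05; 214 and 0 by DESeq2); with a real count of 0 all 100 groupings of each give as many, which says nothing about chance (highest others 26 and 5).

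At 50 pg with RfxCas13d 9594 of 16321 genes passed, among them btg4, buc and dazl upward and most ribosomal protein genes downward (as lists, adjusted p = 0.492 for maternal mRNAs and 0.347 for ribosomal proteins with an estimated correlation). The tables argue against the malat1-rich libraries as the whole cause, since 9259 genes passed without them, and against a loss of long transcripts, since the fold change had a Spearman correlation of 0.02 with relative transcript length (0.01 to 0.12 within 10 classes of expression). Slower development stays open and cannot be told apart from other explanations: the fold change had a correlation of 0.27 with how each gene moves with maternal mRNAs within Cas7-11 groups (0.24 to 0.29 leaving out 1 library), between the bounds of 0.1 and 0.3 set for that test; in other comparisons it was -0.43 (RfxCas13d at 10 pg), -0.13 and 0.05 (DjCas13d at 10 and 50 pg). Unequal handling or clutches of the arms, and a biological effect of the effector with an abundant target, were not tested. The 6 libraries make 10 splits, too few for a share under 0.05: the real split gave 9594 genes and the highest other 3878.

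At 10 pg with RfxCas13d 2281 of 16321 genes passed, mitochondrial and ribosomal protein mRNAs among those lower (as lists, adjusted p = 0.861 each with an estimated correlation), and 2 of the 3 controls were malat1-rich. The count was 1 without the malat1-rich libraries, so their RNA content may be the source of most of these calls; that fit also has only 1 control, which is assumed to vary like the other groups, and fewer samples alone lower a count. With only the RfxCas13d libraries in the fit it was 0 (edgeR, 2810 genes at an unadjusted p under 0.05; DESeq2 on all libraries 3025), so a spread estimated jointly with the other groups may also contribute. An effect of the knockdown stays open: its test is confounded with the malat1-rich controls. GFP was at 676 and 811 TPM in those 2 controls and at 31.2 and 11.3 TPM in malat1-rich replicates 1 and 2 of the DjCas13d knockdown at 10 pg, which argues against exchanged arms, but an exchange of the 2 effector labels at 10 pg, which would change what these values mean for both, was not tested.

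With Cas7-11, 7 genes were lower at both doses, among them ostf1, pdlim1 and iars2. The fold changes of all genes at the 2 doses had a correlation of 0.05, in a test written after the result was seen. No difference between knockdown and control libraries shared by most genes was thus seen. A difference that touches few genes would barely move this correlation, so it is not excluded. A lowering tied to Cas7-11 and its guides stays open: the response of all 7 differed between DjCas13d and Cas7-11 at 50 pg, by 0.81 ± 0.24 (hnrnpm) to 1.82 ± 0.34 (ostf1), adjusted over these genes, but the values that picked them also enter this difference, so it does not decide. Over all genes zgc:100918 alone passed. The RfxCas13d values do not decide either: hnrnpm (-1.69) and zgc:100918 (-0.40) fell at 50 pg, where 4694 of 16321 genes fell, ostf1 and pdlim1 rose there (1.13 each), and the falls of ostf1 (-0.95) and zgc:91910 (-0.77) at 10 pg are in the comparison with malat1-rich controls. The labels give no guide sequences, so matches between guides and these transcripts were not tested.

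With Cas7-11 at 10 pg, 2 of the 35 splits gave as many genes as the real one (12), so chance cannot be excluded by the splits as a whole. The highest other, 558 genes, set replicates 1 and 2 of both arms against 3 and 4 and points to a structure of the samples. Of the 8 splits that part all 4 same-numbered pairs the real one alone gave any gene, the others 0, and with the replicate number as a block 10 genes passed, 9 of them among the 12. These 8 splits are too few for a share under 0.05. The correlations also do not tell the pairs from the sets of replicates 1 and 2 and of 3 and 4. For the following comparisons the splits are too few for a share under 0.05. The real value was 0 and the highest other 1873 with DjCas13d at 10 pg, 1 and 0 with DjCas13d at 50 pg, 10 and 0 with Cas7-11 at 50 pg, 277 and 2098 in the RfxCas13d controls, and 0 and 0 in the DjCas13d controls. The split of 1873 put the 2 malat1-rich libraries with control 3 and that of 2098 put the 3 malat1-rich controls together, which points to a structure of the samples. In the Cas7-11 controls the real count was also 0, so that all 35 splits give as many and nothing is learned about chance (highest other 1264). As many genes as in the real split were given by 1, 10, 1, 1, 4 and 10 of the 10 splits with RfxCas13d at 50 pg, DjCas13d at 10 and 50 pg, Cas7-11 at 50 pg, and the RfxCas13d and DjCas13d controls.

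Single samples stood apart from the others in 5 of 34 sets of 4 values tested. Chance gives about 1 in 20 of independent sets. All these sets came from the control and knockdown libraries of Cas7-11 at 10 pg. They covered library measures and the genes called there. The sets share libraries and include genes picked by the test, so their count cannot be set against chance. A sample was flagged by its gap relative to the range, so a flagged difference can be small. In the Cas7-11 controls at 10 pg malat1 was at 1160 CPM in replicate 2 against 590 to 664, aga at 19.3 CPM in replicate 1 against 24.4 to 25.5, rab14 at 91.3 CPM in replicate 4 against 97.2 to 97.9, and pla2g15 at 44.7 CPM in replicate 2 against 56 to 57.4. In the knockdown zgc:91910 was at 120 CPM in replicate 3 against 95.4 to 97.8. No explanation of these was tested.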

How the results depend on the processing

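Fits without the malat1-rich libraries and with only 1 effector were tests chosen only after the result was seen. Over settings other than leaving out 1 library, 269 results of named genes gave 2444 values: 1978 kept direction and side of the threshold, 445 lost the threshold, 6 gained it and 15 changed sign. Leaving out 1 library gave 1411 kept, 336 lost, 3 gained and 8 reversed of 1758. The 35 gene list results gave 175 values, of which 118 kept their side and 57 lost it. Where not stated below, the cause was not tested.

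The count with RfxCas13d at 10 pg (2281) was 1475 without a filter, 348 with the replicate number as a block, 0 with only the libraries of the 2 groups, 0 with only the same effector, and 1 without the malat1-rich libraries; leaving out 1 library gave 133 (knockdown replicate 1) to 4522 (control replicate 2). Fewer samples enter the last 3 and these. At 50 pg (9594) it was 6012 with only the libraries of the 2 groups and 7998 to 9915 leaving out 1 library. With DjCas13d at 10 pg (0) it was 1 with DESeq2 size factors, 104 by DESeq2, 2 and 4 by limma with an offset of 1 and 0.1, and 0 to 2643 (without knockdown replicate 3). At 50 pg (1) it was 2 with the block, 42 by DESeq2, 2 by limma (offset 1), 979 with only the libraries of the 2 groups, 0 with the same effector, 24 without the malat1-rich libraries, and 0 (without knockdown replicate 2 or 3) to 1.

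With Cas7-11 at 10 pg (12) it was 28 by DESeq2, 19 without the malat1-rich libraries, and 7 (without knockdown replicate 4) to 11. At 50 pg (10) it was 31 by DESeq2, 2 and 3 by limma, 16 without the malat1-rich libraries, and 4 (without knockdown replicate 2) to 7. The dose difference of RfxCas13d (6645) was 4345 without the malat1-rich libraries and 5104 to 7473 leaving out 1; that of DjCas13d (0) was 1 without a filter, 214 by DESeq2, and 0 to 2287 (without 10 pg knockdown replicate 3); that of Cas7-11 was 0 in all edgeR and DESeq2 settings. DjCas13d against Cas7-11 (1) was 0 without a filter, 0 with the block, 22 by DESeq2, 4 without the malat1-rich libraries, and 0 to 1 leaving out 1. RfxCas13d against DjCas13d ranged from 4229 to 6669 and against Cas7-11 from 6045 to 8219. The RfxCas13d controls (277) gave 146 without a filter, 693 by DESeq2, 0 without the malat1-rich libraries (edgeR, 1717 at an unadjusted p under 0.05), and 20 to 1215.

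With an estimated correlation, 2 lists passed with RfxCas13d at 50 pg and 0 in each of the other 5 comparisons; by fry 20 passed with RfxCas13d at 50 pg (15 by camera), 2 at 10 pg and 0 in the DjCas13d and Cas7-11 comparisons. With the block 5 lists passed with DjCas13d at 10 pg, and with library size alone 2 at 50 pg. With library size alone the medians with RfxCas13d at 50 pg turned positive or 0 for RNA decay factors (-0.22 to 0.40), oxidative phosphorylation (-0.44 to 0.17), cell cycle (-0.58 to 0), mitochondrial mRNAs (-0.11 to 0.52) and apoptosis effectors (-0.12 to 0.45), where the median of all genes moved by 0.636.

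Reversed without the malat1-rich libraries were antxr1c in the RfxCas13d controls (0.17), atf3 (0.59), ddit3 (-0.26) and cdkn1a (-0.12) with RfxCas13d at 10 pg, and mdm2 (-0.24) and hsp70l (-0.23) at 50 pg. Hspa4a at 50 pg was 0.01 with library size alone and 0.18 and 0.18 by limma, and nfkbiab 0.02 and 0.02 by limma. Atf3 at 10 pg was 0.12 with library size alone, 0.03 with the block, 0.13 and 0.14 by limma, and 0.13, 0.09 and 0.52 without control replicate 1 or 3 or knockdown replicate 1 (lowest -0.86, without knockdown replicate 2). Leaving out control replicate 1 or 2 or knockdown replicate 3 at 50 pg gave mdm2 at -0.22, -0.15 and -0.07 (highest 0.80, without control replicate 3), and leaving out control replicate 1 or 3 gave hsp70l at -0.20 and -0.13 (highest 3.88, without control replicate 2). None of mdm2, hsp70l at 50 pg, or atf3, ddit3 and cdkn1a at 10 pg passed with all libraries. The test of miR-430 sites was not run. Depth was 17.4 to 24.0 (in 1e6 reads) with Cas7-11 and 3.945 to 8.034 elsewhere, so genes of few reads are better measured with Cas7-11.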

Other observations

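Bckdk, the kinase that holds back breakdown of branched-chain amino acids, fell at both doses of RfxCas13d (-0.72 ± 0.19 and -1.45 ± 0.17, adjusted p = 0.0146 and 2.73e-08) and at 50 pg of DjCas13d. At 10 pg of DjCas13d it did not pass. With Cas7-11 it was at -0.08 ± 0.14 and -0.11 ± 0.17 (adjusted p = 1 each). With RfxCas13d 1139 of 16321 genes fell at 10 pg and 4694 at 50 pg, so a fall of 1 chosen gene at 50 pg is not unusual. These values were chosen after the call with DjCas13d was seen; without the malat1-rich libraries the value with RfxCas13d at 10 pg was -0.66 and did not pass.

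Nanog, a maternally supplied pluripotency factor chosen after its values were seen, rose by 4.70 ± 0.55 with RfxCas13d at 50 pg (adjusted p = 5.28e-08) and was at 0.77 ± 0.48 with DjCas13d at 50 pg (adjusted p = 0.632). Buc was at 10.5 ± 1.09 CPM (SD, n = 3) in the 50 pg DjCas13d controls and 26.1 ± 4.09 CPM in the knockdown (edgeR adjusted p = 0.39). The maternal mRNAs as a list had a median of 0.14 in that comparison and did not pass (camera, adjusted p = 0.312). Across genes, the fold changes with RfxCas13d and DjCas13d at 50 pg had r = 0.40, against -0.10 for RfxCas13d and Cas7-11 and 0.00 for DjCas13d and Cas7-11. Unlike comparisons also correlated: r was 0.27 and -0.21 for RfxCas13d at 10 pg with Cas7-11 at 50 and 10 pg, and -0.26 between the doses of DjCas13d, so 0.40 alone does not set these 2 effectors apart.

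GFP in the 10 pg RfxCas13d controls was at 676 and 811 TPM in the malat1-rich replicates 1 and 3 and at 4463.9 TPM in replicate 2.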
